A study of Mus musculus with 4 samples.

How the data were processed

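ATAC-seq was carried out on untreated primary mouse cells. Per the labels' protocols, DN3 thymocytes were obtained from the thymus by magnetic depletion followed by flow sorting, and naive CD4 T cells from the spleen with a magnetic bead kit, each from Scd1-deficient mice and littermate controls. Nuclei were prepared and libraries amplified by PCR. Samples were grouped by the genotype and cell type labels into 4 groups of 1 library. The labels do not say how many animals each library holds.

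The submitters' processing notes name Trimmomatic for read trimming, BWA for alignment, MACS2 for peak calling and the genome build mm10, with no versions. The settings of MACS2, the handling of duplicate reads and any shift of reads for the Tn5 insertion site are not given in the sources used here. The narrow peak lists deposited by the authors were called for each sample separately. Each deposited peak has a score, which equals 10 times its −log10 q cut to a whole number in over 99.99% of peaks of each list and lies within 1 score unit of it in all. The fold in the deposited lists is the ratio of the fragment pileup at the summit to the local background of the same library. The deposited −log10 p and −log10 q also belong to the summit within its own library and grow with its depth. These are the authors' values and were used only to describe, rank or filter peaks within a list. The highest q, that of the weakest peak, was 0.048 or 0.049 in each list. The position of the summit, also deposited, was used to say which gene it lies in.

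No total read count was used here. From each peak's fold and −log10 p, the whole number of fragments at its summit was recovered, within a tolerance of 0.05, for 100% of the peaks of each list, and with it the lowest local background. About 25.15% to 26.79% of peaks lay within 0.01% of this lowest value, which is taken as the genome-wide background pileup and should scale with depth times fragment length. The narrowest region of a list was assumed to follow its fragment length, which was not measured here. On that assumption, background per bp of narrowest region gave a rough depth ratio of knockout to control of 0.961 in DN3 and 0.873 in naive cells. PCR duplicates may be among the fragments, so intervals cover counting error only, and a deeper or more enriched library lists more weak regions.

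No peaks overlapped within a list, so each peak was 1 region. Regions on chromosomes 1 to 19 and X were compared. The Y chromosome held 14 and 13 peaks in the DN3 control and knockout and 9 and 12 in the naive lists, and was left out. A region was called shared when at least 1 bp overlapped a region of the other list. Shares have Wilson 95% intervals. The Jaccard index divided shared by joint base pairs. With 1 library per group no test was run and no p-value was computed.

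Genes came from a RefSeq table of the assembly GRCm38.p6, the same assembly as mm10, with 21631 protein-coding genes on the compared chromosomes. The planned promoter window needed the strand of each gene, which the table does not give. A gene-end region was therefore defined as a region within 1 kb of either annotated end of the gene, so start and end of transcription are not told apart and start sites inside a gene are missed. With the gene ends shifted by 100 kb, 25.7% and 25.4% of genes had such a region in the DN3 control and knockout and 18.4% and 19.0% in the naive control and knockout, against 66.7%, 66.5%, 57.0% and 58.6% at the real positions. Exons and introns were not annotated here.

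For gene lists, a region belonged to a gene when it lay within the gene body or 10 kb on either side. The 23 lists, with 465 symbols, were written before the data were examined. They cover fatty acid synthesis, cholesterol synthesis, fatty acid oxidation, T cell genes, signalling and stress genes, markers of other cell types and housekeeping genes. Of these symbols 457 matched the table, 2 of them through an older name. Several genes stand in more than 1 list. The balance of a list was compared with 10000 random gene lists of the same size matched on the number and strength of regions. The percentile describes these libraries and is not a p-value.

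The genes and regions named were set by a rule also fixed before the data were examined. Per cell type and direction it takes the 10 strongest regions without a counterpart, each with its nearest gene, meaning the one with the nearest annotated end, which need not be the gene that holds the summit, the 5 genes with the largest difference in the number of regions, up to 3 list members per list and direction whose gene-end call differs, and Scd1. A region and a list member that the rule or the lists take are not reported here. Members of the lists given as examples of calls that agree between genotypes, and the genes of the comparison between cell types, were chosen after their values were seen.

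The overlap and list steps were tested on simulated data. After 2000 of the 76814 DN3 control regions and 2000 of the 46576 naive control regions were removed from a copy of the list, 100% of them and 0% of the kept regions were found without a counterpart. Simulated pileups were recovered for 100% of 4988 summits. Of 8 simulated lists of 25 genes with added knockout-only regions, 8 were above percentile 95, and of 40 unchanged lists 3 were outside percentiles 5 to 95.

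Alternatives were the overlap that counts as shared, stricter strength thresholds, lists of the same length, autosomes alone, other windows around genes, and, chosen after the data were seen, a width of at least 500 bp and the gene end with the stronger region. Motif shares were planned and not run, since no genome sequence was used here. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.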

Results

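Chromatin accessibility was measured by ATAC-seq, which uses the Tn5 transposase to cut and tag open DNA, in cells taken directly from mice. The cells were DN3 thymocytes, an early stage of T cell development in the thymus that carries CD25 but neither CD4 nor CD8, and naive CD4 T cells of the spleen, which have left the thymus and not yet met antigen. Both were isolated from mice lacking Scd1, the stearoyl-CoA desaturase that makes monounsaturated fatty acids, and from littermate controls. The sample titles mark the controls HZ, which the labels do not explain, so whether the controls carried only intact copies of Scd1 is open. There were 4 libraries, 1 per genotype and cell type, so the genotypes have no replicates within a cell type and each cell type has 1 library of each genotype. No p-value is given, and Wilson 95% intervals cover counting error only. The comparisons ask which accessible regions differ between the genotypes in each cell type, and between the cell types. A region means a peak of the authors' list, and a region called in only one list is described as that and not as a change.

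The DN3 lists held 76828 peaks in the control and 76450 in the knockout, and the naive CD4 lists held 46585 and 51309. On chromosomes 1 to 19 and X, which were compared, the DN3 lists had 76814 and 76437 regions covering 59.84 and 57.83 Mb, and the naive lists 46576 and 51297 regions covering 44.93 and 42.13 Mb. The naive knockout list thus had more regions over a shorter length. Its median width was 732 bp against 894 bp in the naive control, and the narrowest region was 225 bp against 275 bp. The DN3 lists were closer, with median widths of 666 and 645 bp in the control and the knockout. Read depth was not given, and the background pileup recovered from the peak statistics served in its place. It was 4.721 and 4.474 fragments in the DN3 control and knockout and 5.116 and 3.653 in the naive control and knockout.

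Scd1 itself, on chromosome 19 from 44394450 to 44407709 (mm10), had a region over its higher-coordinate end in all 4 libraries. In the DN3 control that region spanned 44407152 to 44408706, with a −log10 q of 75.8 in its own list, and in the DN3 knockout 44407155 to 44408827, with 50.8. In the naive control it spanned 44406551 to 44408643, with 25, and in the naive knockout 44406977 to 44408833, with 19. A region inside the gene, from 44396097 to 44396426, was called in the DN3 knockout alone, with a weak −log10 q of 3.51. Within 50 kb of the gene, further regions called in one genotype alone were 44457578 to 44457808 in the DN3 knockout and 44418955 to 44419297 in the naive knockout. A region over the latter place was called in both DN3 libraries. The labels do not say which part of Scd1 was deleted, so a region at the gene end does not check the genotype.

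**Figure D1:**
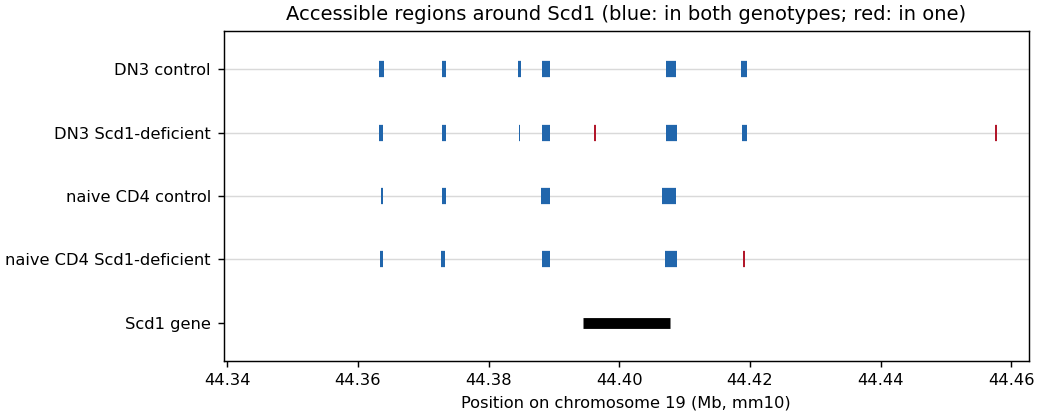
Accessible regions of the 4 libraries along chromosome 19 around Scd1, with position in Mb (mm10) on the horizontal axis and 1 row per library. Blue boxes are regions with a counterpart in the other genotype of the same cell type, red boxes are regions without one, and the black bar is the gene, whose higher-coordinate end lies under a region in all 4 libraries.

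In DN3 thymocytes the strongest regions called in the control alone lay inside Armc8, Nr3c1 (the glucocorticoid receptor) and Gys2 (the liver glycogen synthase). Another lay near Sec61g, a subunit of the protein translocation channel. The Armc8 region, on chromosome 9 from 99563698 to 99564022, had a −log10 q of 85.1 and a fold of 7.14. The Nr3c1 region, on chromosome 18 from 39460887 to 39461192, also had 85.1, with a fold of 11.6. The next regions of this kind were nearest to Mocs1, Dlg2, 4932414N04Rik, Ttpal, Zc3h12c and Ppp1r42, with −log10 q from 80.4 down to 68.5. Among the strongest regions called in the knockout alone were those inside Ubn2 (68.7) and 1660 kb from Slc10a2, its nearest gene (67.4). The others that followed, with 65.8 down to 58.8, lay inside Apbb1ip, an adaptor of integrin activation, Ppp1r13b and Rac1, a GTPase of the actin cytoskeleton, 999 kb from Adam6a, and inside H13, Lats1 and Wdr83, where the nearest annotated gene ends were those of Mcts2, Pcmt1 and Dhps. Of the 10 strongest such regions on each side, the Apbb1ip and Ppp1r13b regions, at 509 and 564 bp, were the only ones of at least 500 bp.

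Over all DN3 regions, 7975 of 76814 control regions had no counterpart in the knockout, which is 10.4% (95% interval 10.2 to 10.6). In the other direction it was 7250 of 76437, or 9.48% (9.28 to 9.7). The regions without a counterpart were weak and narrow. Their median −log10 q was 6.307 in the control against 40.6 for shared regions, and 5.347 against 35.82 in the knockout. Their median width was 296 bp against 724 bp in the control, and 288 bp against 695 bp in the knockout. Among DN3 regions at least 500 bp wide, a width chosen after the data were seen, 1.62% of the control and 1.24% of the knockout regions lacked a counterpart. Of regions with a −log10 q of at least 10, 3.5% and 2.6% did.

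Some genes gathered several DN3 regions of one genotype. Hivep3, a zinc finger protein gene, had 13 control-only and 4 knockout-only regions within its body and 10 kb on either side, beside 40 shared ones. Apbb2 had 7 and 0, Msi1, an RNA-binding protein gene, 8 and 1, Jazf1 7 and 1, and Rad51b, a gene of recombination repair, 7 and 1. In the other direction Arhgap26 had 2 control-only and 9 knockout-only regions beside 51 shared ones. Maml2, a coactivator of Notch, had 2 and 8, Akap13 1 and 7, Sox5 2 and 7, and Cacna1d, a calcium channel gene, 1 and 6. These genes were taken for the size of their difference, and no test bears on any of them.

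At gene ends the DN3 lists of the genotypes were nearly alike. Of 21631 protein-coding genes, 14435 in the control and 14393 in the knockout had a region within 1 kb of an annotated end. Both genotypes had one at 14196 genes, the control alone at 239 and the knockout alone at 197. The gene-end regions of one genotype were weak, with a median −log10 q of 6.31 in the control and 5.8 in the knockout against 185 in the control at genes called in both. Among members of the fixed gene lists, the control alone had a gene-end region at Cd74 (6.25) and Pax5 (1.94), both B cell genes, at Gzmb (8.38), which encodes granzyme B, at Axin1 (6.98), a brake on Wnt signalling, at Psmb11 (7.67), the thymus proteasome subunit, and at Pdgfra (5.64). The knockout alone had one at Cd79a (3.36), the B cell receptor chain, at Itgax (15.5), which encodes CD11c, at Cdh5 (6.0) and at Txnrd1 (11.1), a thioredoxin reductase.

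None of the lipid lists had a member whose gene-end call differed between the DN3 genotypes. Of 28 fatty acid synthesis and desaturation genes, 23 had a gene-end region in both, among them Scd2 (−log10 q of 125 in the control and 137 in the knockout), Fasn, the fatty acid synthase (250 and 256), Acaca (282 and 261) and Srebf1 (166 and 146). The counts were 20 of 23 for cholesterol synthesis and 22 of 24 for fatty acid oxidation and lipid storage. All 29 matched Notch and pre-TCR genes, including Notch1, Ptcra, Rag1 and Rag2, and all 23 T lineage transcription factors, including Tcf7, Bcl11b and Gata3, were called in both genotypes. Each list was also described by its balance, the number of knockout-only minus control-only regions around its genes as a percentage of all its regions. The myeloid and dendritic list had 15 control-only and 4 knockout-only regions of 83, a balance of −13.3% at percentile 0.425 of 10000 matched random lists. The AP-1 and immediate early list had 13 and 6 of 99, at −7.07% and percentile 4.21. Housekeeping genes had 0 and 6 of 63, at 9.52% and percentile 98.1. The other 20 lists lay between percentiles 5.7 and 89.0. Of the unchanged simulated lists, 3 of 40 were outside percentiles 5 to 95, so some of 23 lists would lie there by chance. With 50 kb around each gene body, the myeloid list moved to percentile 8.03 and the AP-1 list to 53.4, and housekeeping genes stayed at 96.1. At the same number of strongest regions the AP-1 list was at 22.7, the myeloid list at 0.3 and housekeeping genes at 97.7.

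In naive CD4 T cells the strongest regions called in the control alone lay inside Rnf130 (chromosome 11, 50114361 to 50114725, −log10 q of 103, fold 18.3), inside Actr10 (96.3), a dynactin subunit gene, and inside Mtmr7 (66.6). Then came regions nearest to Cbln3, Tmem30a, Syngr1, Frs2, Vmn2r129, Rps6ka1 and Tbcel, with 62.1 down to 51.6. The strongest knockout-only region lay on chromosome 12 from 3109872 to 3110110, outside genes and 137 kb from Rab10, with a −log10 q of 2920 and a summit pileup of 2527 fragments. The next were inside Chl1 (716), 263 kb from Mc2r (235) and 1030 kb from Lrrc4c (185), the last with a fold of 2.14 on a pileup of 1877 fragments. The regions assigned to Rab10, Lrrc4c and Alkbh8 lie in or near segments known to gather reads of repeated sequence in mm10, and no list of such segments was used here to remove them. Regions nearest to Epm2a, Alkbh8, Map2k3, a kinase of the p38 pathway, Syt11, Ostm1 and Psph followed, with 141 down to 72.1, and the last of these lay inside Cct6a. None of the 10 knockout-only regions named reached 500 bp, and 8 were narrower than 275 bp, a width below which the naive control list holds no region. Of these 10, 8 were called in both DN3 libraries, including those near Rab10, Chl1, Mc2r and Lrrc4c.

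In naive cells 2686 of 46576 control regions, or 5.77% (5.56 to 5.98), had no counterpart in the knockout. In the other direction 6346 of 51297 knockout regions, or 12.4% (12.1 to 12.7), had none in the control. The median −log10 q of these regions was 6.134 against 59.94 for shared ones in the control, and 7.387 against 52.29 in the knockout. With both lists kept to the same number of strongest regions, the shares became 9.64% for the control and 7.91% for the knockout. At equal length the shares can differ only through regions that overlap several of the other list. In the full lists 1085 control regions spanned 2 or more knockout regions, against 44 the other way. The turned order is therefore no reversal between the genotypes. Among regions of at least 500 bp, 1.81% of control and 2.01% of knockout regions lacked a counterpart.

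**Figure D2:**
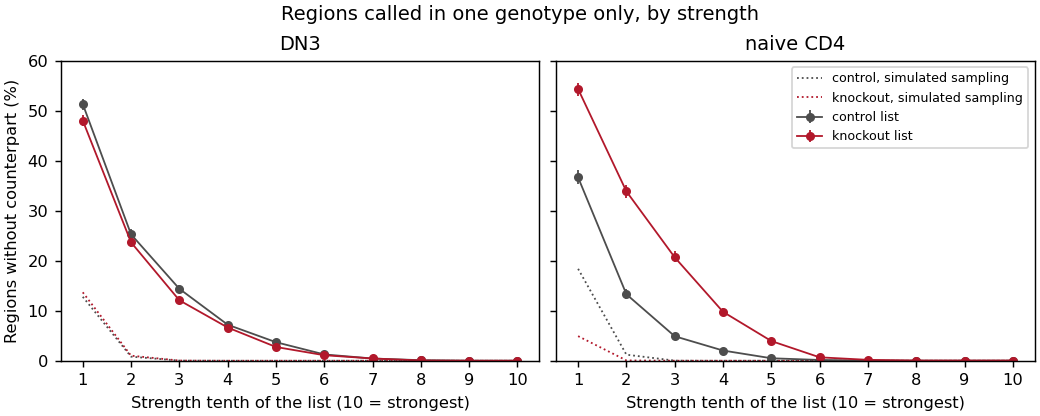
Share of regions without a counterpart in the other genotype, in percent, against strength class within the list (1 weakest, 10 strongest by −log10 q), for DN3 and naive CD4 cells. Points are the observed shares with Wilson 95% intervals and dotted lines are simulated sampling of the same summits. In the weakest class the shares were 51.4% and 48.1% in DN3 control and knockout and 36.7% and 54.4% in naive control and knockout, and in the strongest class at most 0.039%.

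The naive control had more regions of its own around Ptprc, which encodes the phosphatase CD45, with 8 control-only and 2 knockout-only regions beside 18 shared ones. Thada had 5 and 1, Foxp1, a factor that keeps T cells quiescent, 7 and 3 beside 64 shared, Pde3b 6 and 2, and Ctnnd1 4 and 0. The knockout had more around Akap13, with 0 control-only and 8 knockout-only regions, which was also among the DN3 genes with more knockout-only regions. The others were 2900026A02Rik with 0 and 7, Gse1 with 3 and 9, Sik3 with 2 and 8, and Etv6, an ETS family repressor, with 1 and 7.

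Gene ends in naive cells were called at 12337 genes in the control and 12674 in the knockout, with 12257 in both, 80 in the control alone and 417 in the knockout alone. With both lists at the same number of strongest regions these became 163 and 243. Among list members, the knockout alone had a gene-end region at Rag1, the recombinase of receptor gene rearrangement (13.1), Kit, the stem cell factor receptor (9.75), Meis1 (6.64) and Zbtb16, the factor PLZF of innate-like T cells (4.53). The same held for Pdgfrb (11.4), Fzd6, a Wnt receptor (5.91), Mlxipl, the glucose-responsive factor ChREBP (6.64), Pparg (2.65) and the B cell gene Fcer2a (2.65). All 9 of these had a gene-end region in both DN3 libraries. This is near the share over all genes, since 12547 of the 12674 genes called in the naive knockout were also called in the DN3 knockout. Gzmb (9.75) was also called in the naive knockout alone, and of the DN3 libraries only in the control. The control alone had Cpt1b, a carnitine palmitoyltransferase of fatty acid oxidation (5.65), which had none in the DN3 libraries, and Ifi44 (2.23), which had one in both (185 and 203). Of the fatty acid synthesis genes, 22 of 28 were called in both naive genotypes, and Mlxipl was the member that differed.

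Since the naive knockout list was longer, the median balance of matched random lists was above 0, for example 5.37% for lists matched to the T lineage transcription factors. Of the lists of T cell genes, 5 were under percentile 5, but without the genes they share, a check chosen after the data were seen, only naive homing and quiescence (3.41) and CD8 and double-positive markers (2.94) stayed there, with Notch and pre-TCR genes at 20.6, T lineage factors at 14.2 and TCR signalling at 13.6. T helper and effector genes (percentile 21.1) and gamma-delta T cell markers (70.1) lay within the range of random lists. The 23 T lineage transcription factors had 39 control-only and 37 knockout-only regions of 434, a balance of −0.461% at percentile 1.52. Notch and pre-TCR genes had 11 and 9 of 163 (−1.23%, percentile 0.92), and naive T cell homing and quiescence genes 26 and 26 of 331 (0.0%, percentile 2.56). TCR signalling genes had 36 and 39 of 330 (0.909%, percentile 3.46), and CD8 and double-positive thymocyte markers 6 and 4 of 85 (−2.35%, percentile 2.1). Unfolded protein and oxidative stress genes had 7 and 5 of 89 (−2.25%, percentile 1.95). In the other direction, cholesterol synthesis genes had 1 control-only and 10 knockout-only regions of 63, a balance of 14.3% at percentile 97.5. The other 16 lists lay between percentiles 13.1 and 89.4. With lists of the same number of regions, cholesterol synthesis moved to percentile 77.6, Notch and pre-TCR genes to 16.5, CD8 and double-positive markers to 8.48 and stress genes to 5.34, and the TCR signalling balance turned to −12.5% at percentile 1.16. T lineage factors (0.42) and naive homing (0.38) stayed under percentile 5, and interferon response genes came under it (4.32). With 50 kb around each gene body, cholesterol synthesis was at 91.5 and Notch and pre-TCR genes at 8.2. The other 5 low lists stayed between 1.19 and 4.71, and Wnt signalling genes came under percentile 5 (3.54).

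**Figure D3:**
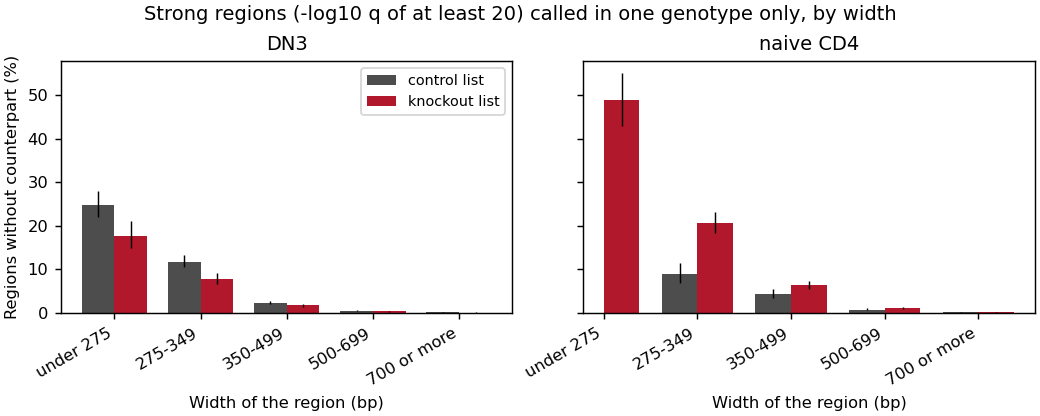
Share of strong regions, those with a −log10 q of at least 20, that had no counterpart in the other genotype, in percent, by region width in bp. Bars are control (grey) and knockout (red) lists with Wilson 95% intervals. The share was highest in the narrowest class, 24.8% and 17.7% in DN3 control and knockout and 49% in naive knockout, where the naive control list had no region, and was at most 0.0468% at 700 bp or more.

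Lists of different cell types overlapped less than lists of different genotypes. The Jaccard index, the shared length over the joint length of 2 lists, was 0.768 between the DN3 genotypes and 0.773 between the naive genotypes. Between DN3 and naive cells it was 0.478 in the controls and 0.502 in the knockouts, and 0.493 and 0.484 across genotypes. Of 90270 joint regions, 37418 (41.5%) were called in all 4 libraries, 25536 (28.3%) in both DN3 libraries and neither naive one, and 4613 (5.11%) in both naive libraries and neither DN3 one. Of control DN3 regions 47.2% had no naive counterpart, against 15% in the reverse direction, and in the knockouts it was 43.3% and 16%. With all lists at the same number of strongest regions, the control shares became 29.6% and 30.1% and the knockout shares 27.8% and 27.7%. Lists of the same length must give nearly equal shares in both directions, so this cut cannot show why the full lists differ.

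**Figure D4:**
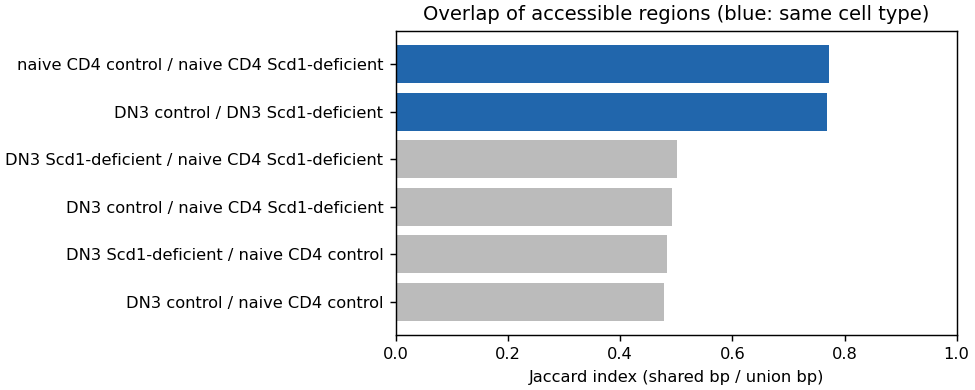
Jaccard index, shared base pairs over joint base pairs, for the 6 pairs of libraries. Blue bars are pairs of the same cell type, at 0.768 and 0.773, and grey bars are pairs of different cell types, from 0.478 to 0.502.

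Of the 29 Notch and pre-TCR genes of the DN3 stage, 4 had gene-end regions in both DN3 libraries and neither naive one, 24 had them in all 4 libraries and Rag1 in all but the naive control. The 4 were Spib, Ptcra, which encodes the pre-TCR alpha chain (−log10 q of 121 in the control and 130 in the knockout), Rag2 (60.8 and 49.8), and Dntt, the terminal transferase (16.4 and 31.4). Lmo2 (71.9 and 52.4) and Gata2 (21.0 and 21.9), factors of multipotent progenitors, and Cd8a (34.6 and 23.2) followed the same pattern. They were 2 of 16 early progenitor and 1 of 13 CD8 and double-positive markers, of which 11 and 10 were called in all 4 libraries. Itgae, of the naive homing list, was also called in both DN3 libraries and neither naive one (6.09 and 9.1). In both naive libraries and neither DN3 one were Il2, the interleukin 2 gene (40.1 and 35.1), Tnfrsf4, which encodes OX40 (99.4 and 75.5), Foxp3, the regulatory T cell factor (9.78 and 10.1), and Dapl1 (8.0 and 17.7). In all, 1637 genes had a gene-end region in DN3 cells alone, 75 in naive cells alone and 12131 in both, alike in both genotypes.

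Among the genes with the most regions restricted to naive cells, Inpp4b, a phosphoinositide phosphatase gene, had 28 naive-only and 0 DN3-only regions, Bach2, a repressor that preserves naive cells, 16 and 5, and Lef1, a TCF family factor, 11 and 0. Foxp1 had 18 and 9, Bcl2, the survival factor, 10 and 3, Tox 9 and 2, Ptprc 8 and 0, and Sgms1, a sphingomyelin synthase gene, 12 and 2. Genes with many regions restricted to DN3 cells included Gse1 with 33 against 1, Hivep3 with 28 against 1, Maml3, a Notch coactivator, with 26 against 0, Zfhx3 with 25 against 0 and Ephb2 with 22 against 0.

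By gene list, DN3-only and naive-only regions numbered 60 and 95 for T lineage transcription factors, 30 and 86 for naive homing and quiescence, 33 and 47 for TCR signalling, and 14 and 22 for apoptosis and survival. These 4 lists were at percentile 100 after rounding among matched random lists, whose balance favoured DN3 cells. They are not independent. Foxp1 (18 naive-only regions), Bach2 (16), Foxo1 (5) and Satb1 (5) count in both the T lineage and the naive homing list. Bcl2 (10) counts in both the naive homing and the apoptosis list. The percentiles between cell types were not computed without shared genes. T helper and effector genes had 43 and 27 (percentile 99.8), housekeeping genes 3 and 4 (99.6) and interferon response genes 15 and 8 (96.0). Gamma-delta T cell markers had 34 and 2 (percentile 3.47), with Zbtb16 holding 15 of the DN3-only regions and Blk 7. Stromal and epithelial markers had 22 and 0 (3.06). The other lists lay between percentiles 11.1 and 92.5. They were Notch and pre-TCR genes with 69 and 6, Wnt signalling with 57 and 17, fatty acid synthesis with 50 and 7, early progenitor markers with 41 and 2, and B cell markers with 36 and 4. Cell cycle genes had 34 and 8, fatty acid oxidation 34 and 2, CD8 and double-positive markers 33 and 11, NK and innate lymphoid markers 25 and 5, and cholesterol synthesis 21 and 2. Unfolded protein and stress genes had 19 and 3, myeloid markers 19 and 4, AP-1 genes 12 and 1, and erythroid and platelet markers 4 and 1.

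**Figure D5:**
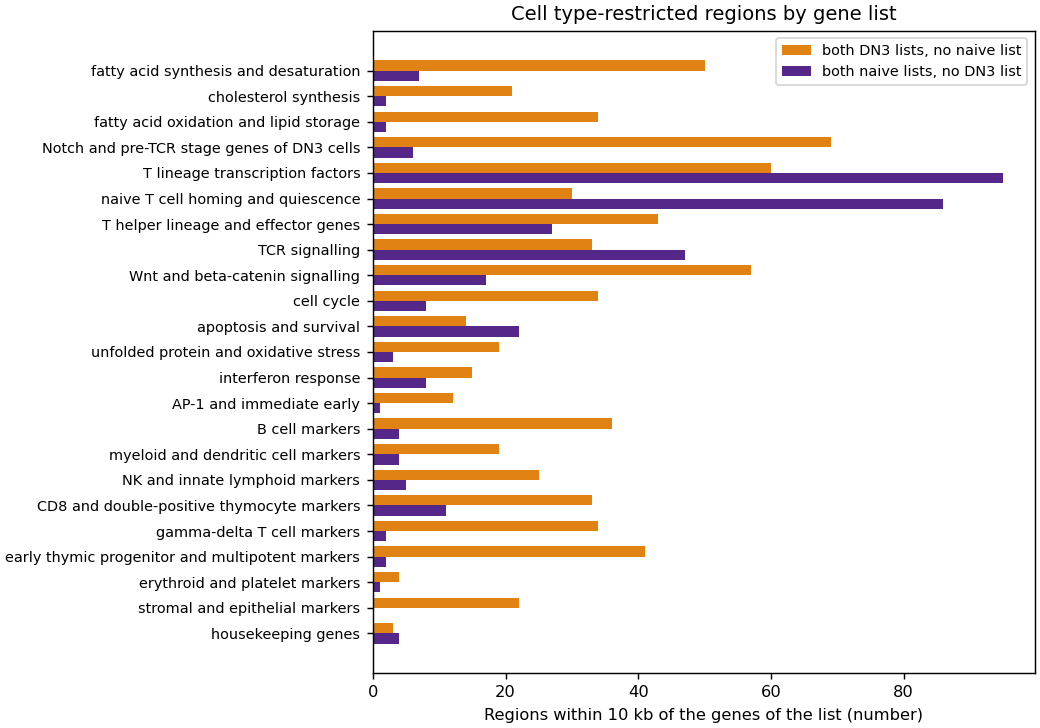
Number of regions restricted to a cell type within 10 kb of the genes of each fixed list. Orange bars are regions in both DN3 lists and no naive list, purple bars regions in both naive lists and no DN3 list. Purple exceeds orange for T lineage transcription factors (95 and 60), naive homing and quiescence (86 and 30), TCR signalling (47 and 33), apoptosis and survival (22 and 14) and housekeeping genes (4 and 3).

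Genotype-restricted regions of the cell types were set against each other at the 44765 joint regions called in both cell types. Of these, 149 were called in the control alone in both DN3 and naive cells, against 137 for independent lists matched on strength, and 345 in the knockout alone in both, against 357. Regions of opposite genotype in DN3 and naive cells were as near to that number, with 329 against 331 and 153 against 151. The labels do not say whether the DN3 and naive libraries of a genotype came from the same animals.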

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

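Several measures of the difference between genotypes had opposite signs in DN3 and naive cells. With 1 library per group none of these differences between cell types was tested. Of the tests below, those of chance sampling, of width at matched strength, of genotype, of depth, of regions under 275 bp and of gene ends were chosen after the result was seen. The tests of DN3 cell DNA below and of a difference shared by the cell types were first read by their point values as not fitting, and were read by their intervals, as open, only after the values were seen.

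In DN3 cells the knockout had fewer regions than the control (−377), and in naive cells more (4721). Genes with a gene-end region in the knockout alone minus those in the control alone numbered −42 in DN3 and 337 in naive cells. The balance of T lineage transcription factors was 0.484% in DN3 and −0.461% in naive cells, and that of TCR signalling genes −3.45% and 0.909%. For AP-1 and immediate early genes it was −7.07% and 4.23%, for myeloid and dendritic markers −13.3% and 1.79%, and for CD8 and double-positive markers 2.48% and −2.35%. The naive balances sit on a list with more knockout regions. Among matched random lists, TCR signalling (percentiles 15.8 in DN3 and 3.46 in naive cells) was under percentile 5 in naive cells alone. So were T lineage factors (75.3 and 1.52) and CD8 and double-positive markers (79.1 and 2.1). AP-1 genes (4.21 and 32.4) and myeloid markers (0.425 and 19.5) were under it in DN3 cells alone. The other percentile of each list lay within the range of random lists. These percentiles therefore show neither agreement nor opposition of the cell types. At the same number of strongest regions the DN3 and naive balances had the same sign for TCR signalling (−3.45% and −12.5%), AP-1 genes (−3.09% and −1.45%) and myeloid markers (−13.3% and −1.85%). They stayed opposite for T lineage factors (1.96% and −13.6%) and CD8 and double-positive markers (2.48% and −11.0%). With 50 kb around each gene body these last had the same sign (1.02% and 1.05%, 3.15% and 1.28%). TCR signalling (−2.96% and 1.74%), AP-1 genes (−0.687% and 5.58%) and myeloid markers (−4.53% and 9.03%) were then opposite. None of the lists named in this paragraph was therefore opposite under both alternatives.

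Strong regions called in one genotype, such as those at Nr3c1 in DN3 control and Chl1 in naive knockout, were more numerous than counting error at the summit alone gives. Both examples were narrow, at 306 and 233 bp, and the naive control list holds no region under 275 bp. Over the 4 lists, 1748 regions with a −log10 q of at least 20 had no counterpart, and simulated sampling of the same summits left 0.1 on average. The simulation held counting error only, without PCR duplicates, further variation between libraries or a minimum length of regions. Summits this strong can hardly be lost that way, so it cannot exclude chance differences between the real libraries. At a −log10 q of 20 to 40, regions under 350 bp lacked a counterpart at least 37.1 times as often as regions of 700 bp or more in each list, so regions near the minimum length of a list, which a small difference in width can drop, may account for most of them. Wide regions also meet a counterpart more easily, which this ratio includes. Genotype remains open for the rest, and with 1 library per genotype and cell type it cannot be told apart from differences between libraries.

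For the larger number of naive knockout regions, greater depth is argued against by the background pileup of the knockout, 0.714 times that of the control. This pileup should also scale with fragment length, and per bp of narrowest region the ratio was closer, at 0.873. Neighbouring regions joined in the control and split in the knockout made up 22.5% of the difference, 1061 of 4721 regions, which leaves most of it. Of the remaining excess of 3660 regions, the 2085 knockout-only ones under 275 bp, the narrowest width of the control list, make up at most 57.0%, since at 275 bp or more 4261 knockout-only regions stood against 2686 control-only ones. The excess lay almost wholly in narrow regions, with 5621 and 2011 under 500 bp against 725 and 675 at 500 bp or more, and at that greater width the share without a counterpart was 1.11 times as high in the knockout (95% interval 1.001 to 1.23), which lies between the bounds set for the test, no excess and above 1.2, with an interval that starts just above no excess and passes 1.2. For what remains at 275 bp or more, narrow regions that the control list misses, a more enriched knockout library and a genotype difference therefore cannot be told apart.

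Regions called in the naive knockout alone were more often DN3 regions than those called in the naive control alone. Both were less often DN3 regions than the shared naive regions, which were also stronger. Of shared regions, 85.5% in the naive control list and 84.7% in the naive knockout list were called in both DN3 libraries. In both DN3 libraries were 3691 of 6346 knockout-only regions (58.2%, 56.9 to 59.4) against 1083 of 2686 control-only ones (40.3%, 38.5 to 42.2), and of those at least 500 bp wide 504 of 725 (69.5%, 66.1 to 72.8) against 265 of 675 (39.3%, 35.6 to 43.0). The difference of 30.3 points at this width argues against narrowness as the cause, and 25.3 points away from gene ends argue against signal at gene ends. Of DN3 regions absent from the naive control, the share called in the naive knockout was 6.08% in the weakest of 10 strength classes. It was 18.2% in the next to strongest and 17.3% in the strongest. With the genotypes exchanged these shares were 4.85%, 4.66% and 5.44%. The strongest fiftieth was called 1.02 times (95% interval 0.843 to 1.23) as often as the seventh and eighth classes, 16.6% against 16.3%. The fifth and sixth classes were lower, at 11.7% and 12.7%, so the ratio depends on the classes compared. The ratio was short of the 1.5 set for DNA of DN3 cells in the library and not clear of the 1.2 set against it. Such DNA cannot be told apart from a genotype difference or a more enriched knockout library, and neither of these has another library to test it.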

How the results depend on the processing

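Under the alternatives set before the data were examined 44 values moved and 24 did not, and of those chosen after the data were seen (a width of at least 500 bp, the end with the stronger region) 4 moved and 4 did not. A share moved when it left the 95% interval of the main value, a count when it changed by more than 1.5 times and a Jaccard index when it changed at the digits printed. Unless stated the cause was not tested. Shares without a counterpart are given for DN3 control, DN3 knockout, naive control and naive knockout. A reciprocal overlap of 50% gave 15.5%, 15.1%, 10.8% and 19%, and counting regions within 500 bp as shared 9.51%, 8.74%, 5.43% and 11.9%. A −log10 q of at least 5 in both lists gave 9.81%, 6.93%, 5.46% and 10.3%, and of at least 10 in the list asked about 3.5%, 2.6%, 1.67% and 5.01%. At the same number of strongest regions the DN3 control share was 10.1%, the naive control share 9.64% and the naive knockout share 7.91%. The turned order of the naive shares reflects joined and split regions, since lists of equal length can differ in no other way. At 500 bp or more the shares were 1.62%, 1.24%, 1.81% and 2.01%. Leaving out X moved none of them.

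The Jaccard index at a −log10 q of at least 5 was 0.782 between DN3 genotypes and 0.783 between naive genotypes, and between cell types 0.484 (controls), 0.497 (DN3 control, naive knockout), 0.493 (DN3 knockout, naive control) and 0.509 (knockouts). At the same number of regions these were 0.802, 0.775, 0.507, 0.527, 0.512 and 0.535. Cell type shares at the same number were 29.6% and 30.1% in control DN3 and naive lists and 27.8% and 27.7% in the knockout ones. Naive gene ends called in one genotype became 163 (control) and 243 (knockout) at the same number of regions, while the DN3 counts stayed within 1.5 times under every window, threshold and gene-end choice tried. Regions of one genotype in both cell types became 227 (knockout) at a −log10 q of at least 5, and 227 (control) and 201 (knockout) at the same number of regions. DN3 gene lists under percentile 5 became 0 with 50 kb around gene bodies and 1 at the same number of regions, and naive lists above percentile 95 became 0 under both.

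No paired analysis was run, since the labels give no replicate numbers, and no result comes from a test. A fit of genotype and cell type together over the 4 libraries, which would leave 1 residual degree of freedom, was not run. Leaving out a replicate does not apply, and motif shares were not run. The lower background pileup of the naive knockout and its narrower regions limit what its weak regions can show.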

Other observations

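Of the tests here, that of a difference shared by the cell types was chosen after the result was seen, and that of the segment around Scd1 before.

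Genes of other lineages had gene-end regions in sorted DN3 cells. In both DN3 libraries and neither naive one were Blk, a B cell kinase also found in gamma-delta T cells (−log10 q of 103 in the control and 88.4 in the knockout), Bank1 (18.1 and 15.3) and Vpreb3 (26.3 and 21.4) among B cell genes, and Lyz2, the lysozyme of myeloid cells (28.5 and 32.6). So were Foxn1, the factor of thymic epithelium, and Krt8 (24.1 and 28.9). Genes of this pattern were 4 of 18 B cell, 2 of 20 myeloid and 4 of 15 stromal markers, against 1637 of all 21631 genes. The myeloid share is near that over all genes. The B cell count includes Spib, which is also in the list of Notch and pre-TCR genes of the DN3 stage. In the B cell, myeloid and stromal lists 6, 7 and 4 members were called in all 4 libraries, and 3, 9 and 3 in none. Wnt pathway genes called at a gene end in DN3 cells alone were Fzd1 (48.0 and 37.9), Fzd8 (20.2 and 26.8), Wnt3a (19.5 and 27.5), Wnt4 (19.5 and 15.3), Dkk1 (24.1 and 30.3), Dkk3 (18.1 and 20.9) and Ccnd1 (26.2 and 19.1), which is 7 of the 33 members. All of these were chosen after their values were seen.

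In naive CD4 libraries of both genotypes, gene-end regions stood at Cd79a (54.5 in the control and 53.8 in the knockout) and Cd74 (39.6 and 69.1), both abundant in B cells, and at Itgam (42.3 and 33.4), which encodes CD11b. No gene-end region was called at Ms4a1, Ly6g or Adgre1 in any of the 4 libraries, nor at the globin genes Hbb-bs, Hbb-bt, Hba-a1 and Hba-a2. Actb had a gene-end region in naive cells alone (488 and 351), although 3 regions around it were common to all libraries, which shows the limit of annotated gene ends.

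A genotype difference shared by the cell types would have put regions of one genotype at the same places in DN3 and naive cells. The larger of the observed ratios to lists matched on strength was 1.09, for regions of the control alone (95% interval 0.92 to 1.28), which is not clear of the 1.2 set for the test, and 0.966 (0.867 to 1.07) for the knockout alone. A shared difference therefore cannot be told apart from none in the control and fell short of that bound in the knockout. A segment around Scd1 that differs between the strains would have raised the share of regions of one genotype near the gene. In the 5 Mb window that holds Scd1, from 40 to 45 Mb of chromosome 19, 17.1% of DN3 regions were of one genotype, rank 202 of 323 windows, and 19% of naive regions, rank 59 of 230. The medians over windows were 17.9% and 16.8%, so the hypothesis found no support in either cell type.

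The 5 T cell lists under percentile 5 in naive cells, picked for that, were matched again on the number of regions. They were at percentiles 1.31 (Notch and pre-TCR), 0.69 (T lineage factors), 2.56 (naive homing), 2.44 (TCR signalling) and 2.76 (CD8 and double-positive). This matching kept the genes they share, without which 3 of them left that range.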
